A study of Mus musculus with 34 samples.

How the data were processed

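The series holds 34 samples of mouse liver. Of these, 10 had files that were analysed: 3 mRNA libraries of WT and 3 of KO, and nascent RNA by ethynyl uridine (EU) and by bromouridine run-on (Br) with 1 WT and 1 KO library each. The labels give an age of 45 days, an EU dose of 25 mg per kg given 30 min before death, and a run-on of 3 min. The 24 chromatin and input samples were not analysed here. Groups of the analysed libraries were taken from the sample titles. TopHat2, Bowtie2, Cufflinks, DESeq, MACS2, SICER and genome mm9 are named in the submitters' processing notes. The counter, annotation and filters were not given in the sources used here.

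The mRNA files hold a score: values that the authors scaled between the 6 libraries with DESeq size factors and rounded to whole numbers. Whole numbers are skipped or doubled at a regular step in each library, so reads were re-estimated from that step. For 3 of the libraries the step is under 1, and the re-estimated reads are approximate. The nascent RNA files hold counts per gene as deposited. Every Br value is even, so Br counts were divided by 2 to give reads. The authors also deposited a table of RPKM for the 4 nascent libraries. Its implied gene lengths are the same in the 4 columns (within 0.1% for 16644 of 16689 genes) and often far from transcript lengths. Ratios within a gene can therefore be used, while levels between genes cannot be trusted. Such levels still served for the RPKM floors and for the matching of random lists described below. Gene names came from a GENCODE annotation of a later build, and coordinates were used only for gene order and the genomic span of genes. No pair of mRNA libraries was identical.

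Because raw counts were planned for and the files hold scaled values, the main test was limma-trend in place of edgeR. It used limma 3.58.1 in R 4.3.3 (eBayes with trend and robust) on log2 of the scaled value plus 1, over genes with a value of at least 10 in at least 3 libraries. Genes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The gene lists, the rule for naming genes and the alternatives not named below as added were fixed before the data were examined. Fold changes are those fitted on value plus 1.

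The 45 gene lists held 935 members, 7 of them with no row under any name. They cover liver metabolism, plasma proteins, stress and signalling responses, proliferation, sex-biased and clock genes, liver zonation and markers of other cell types. Lists with at least 5 tested members were tested with camera at a correlation of 0.01, two-sided, Benjamini-Hochberg over 43 lists, and beside it with camera at an estimated correlation and with fry. Counts adjusted over the list alone were computed too.

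Nascent RNA was compared within each method as the log2 ratio of KO to WT of RPKM plus 0.5, over 13213 genes with a mean RPKM of at least 1, centred on the median gene. The median before centring was -0.07 in EU. A list's median was placed among 10000 random lists matched on mean RPKM in 20 bins, and a list was named where both methods lay outside the central 95%. Mean RPKM depends on the implied gene lengths, so the floor and the matching do not pair genes by read number. The alternative with counts in place of RPKM changed the ratios only and kept this floor and matching. Counting intervals at 95% are exact (Clopper-Pearson) and cover counting error only. They use reads without the added 0.5 RPKM, which shrinks ratios of genes at low RPKM, so a ratio can lie outside its interval. In EU, Gstm3 had a log2 ratio of 1.42 and an interval of 2.36 to 4.04. The median kept gene had 256 EU and 147 Br reads over both libraries.

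Genes were named by a fixed rule: Setd8, the 8 called genes with the largest rise and the 8 with the largest fall among those without overlap between groups and with at least 5 CPM, up to 4 called members per list in the direction most called members took and up to 2 in the other, and for nascent RNA 5 genes per direction. Thrsp in nascent RNA followed from the same rule with at least 20 reads, chosen after the values were seen. Some genes that the rule chose are not reported here. Values of gene families with similar sequence, such as Cyp4a, Gst, Ugt2b and H2 genes, are uncertain.

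Alternatives tried for mRNA were edgeR 4.0.16 (RLE and upper-quartile scaling) and DESeq2 1.42.0 on re-estimated reads, no filter, a filter of 1 CPM, a replicate block, a 2-fold minimum and each library left out. Added after the data were seen were edgeR with TMM, edgeR without WT replicate 3, pseudocounts of 0.5 and 10, TMM scaling and array weights. For nascent RNA they were pseudocounts of 0.1 and 2 RPKM, a mean RPKM of 0.2 or 5, ratios not centred and counts in place of RPKM, and, added later, at least 20 reads and mRNA sets without WT replicate 3. Tested on simulated data with the depth and gene-wise spread of these libraries, limma recovered 93 of 100 genes changed 4-fold and 17 of 100 changed 2-fold, with 5 false calls among 16296 genes. Counts were drawn independently for each gene and library. The false calls therefore do not cover shifts that many genes of a library share, such as those of WT replicate 3. Simulated nascent lists shifted 2-fold were named in 20 of 20 cases, lists shifted 1.5-fold in 12 of 20 and lists without a shift in 0 of 40. These lists held random genes with independent noise. They therefore do not measure how often a list is named because its members move together between single animals. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.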

Results

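The series measured RNA of mouse liver at 45 days of age in animals labelled wild type (WT) and in animals labelled knockout (KO) for Setd8, which encodes the histone H4 lysine 20 methyltransferase also called Kmt5a or PR-Set7. The knockout was made with a floxed exon and the Alb-Cre transgene, which is active in hepatocytes. Messenger RNA was sequenced in 3 WT and 3 KO libraries. Newly made RNA was sequenced by 2 methods with 1 WT and 1 KO library each: capture of nuclear RNA labelled in the animal with ethynyl uridine (EU), and a run-on of isolated nuclei with bromouridine triphosphate (Br). A further 24 chromatin samples were not analysed here. The labels number the replicates and do not say more on whether each is a separate animal, so that p-values measure the spread between these libraries, which may in part be technical.

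Scaled values summed to between 18069344 and 25820906 per mRNA library over 37583 genes, and the reads re-estimated from the rounding pattern lay between 15640582 and 27108677. WT replicate 3 had 20077 genes above 0, against 24497 to 26247 in the other 5 libraries. It stood apart on the first principal component, which held 43.9% of the variance, at 121.5 against -46.2 to -6.11 for the others. The second component, with 35.1%, parted the other WT libraries from the KO libraries. EU libraries held 10833287 (WT) and 5583983 (KO) reads, and Br libraries 3156055 and 2317840.

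The first comparison asked whether Setd8 itself was lower in the libraries labelled knockout. Setd8 mRNA (Kmt5a in the annotation, ENSMUSG00000049327) did not fall. Its mean scaled value was 761 ± 273 in WT and 1105 ± 83.5 in KO (SD, n = 3 each), a log2 difference of 0.59 (SE 0.25, limma adjusted p = 0.244). Without WT replicate 3 the difference was 0.87 and passed the threshold (limma adjusted p = 0.0198, with a range of 0.000312 to 0.512 over the alternatives run). Nascent Setd8 RNA had 473 EU reads in WT and 310 in KO, a centred log2 ratio of 0.41 (95% counting interval 0.21 to 0.63), and 104 and 92 Br reads, a ratio of 0.26 (-0.15 to 0.69). Counts over the whole gene test the loss of a single exon only in part, and cells other than hepatocytes keep the gene. The groups are therefore named by their labels throughout, and every direction below is that of libraries labelled knockout against libraries labelled wild type.

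The second comparison asked which mRNAs differed between the labelled groups. Cyp4a14, a fatty acid omega-hydroxylase, rose from a mean of 70.7 ± 17.0 to 25041 ± 5528 (SD, n = 3 each), a log2 fold change of 8.45 (SE 0.24, limma adjusted p = 6.11e-06). Cdkn1a, which encodes the cell cycle inhibitor p21, rose 39.7-fold, with KO values of 2210, 1443 and 518. With a library left out its fold ran from 29.0 to 61.2, and its call was lost without WT replicate 2 or KO replicate 2. The zinc transporter Slc39a5 rose 28.0-fold, and the steroid hydroxylases Cyp17a1 and Cyp2b9 19.1-fold and 16.5-fold. Serpina12 (vaspin) fell 31.9-fold, from 3332 ± 496 to 121 ± 84.9, and the NADPH oxidase gene Nox4 fell 31.5-fold. In all, 227 genes rose and 228 fell among 16813 tested (limma, Benjamini-Hochberg), of which 214 and 211 differed at least 2-fold.

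The other genes with the largest rises were Capn11 (a calpain, log2 5.54), Phlda3 (a p53 target, 4.27) and Fbxo44 (4.16). With a library left out these ran from 4.804 to 6.208, from 3.68 to 5.34 and from 3.41 to 4.76. The other large falls were in Obp2a, with scaled values of 100, 188 and 349 in WT and 0, 1 and 1 in KO, and in H2-Ea-ps of the major histocompatibility region, with 75, 171 and 400 against 1, 1 and 0 (log2 -7.37 to -6.17 with a library left out). For H2-Ea-ps another haplotype of that region in one group stays open, as described below. Dpt (dermatopontin, log2 -5.23), the pseudogene Rps15a-ps8 (-5.08), Mme (neprilysin, -4.87) and Cyp46a1 (-5.87) also fell. For Cyp46a1, WT replicate 3 held 5096 against 213 and 190 in the other WT libraries, and the log2 fold change without it was -4.31, with a range of -6.68 to -4.31 over the libraries left out. The plot of the leading genes shows each library.

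**Figure D1:**
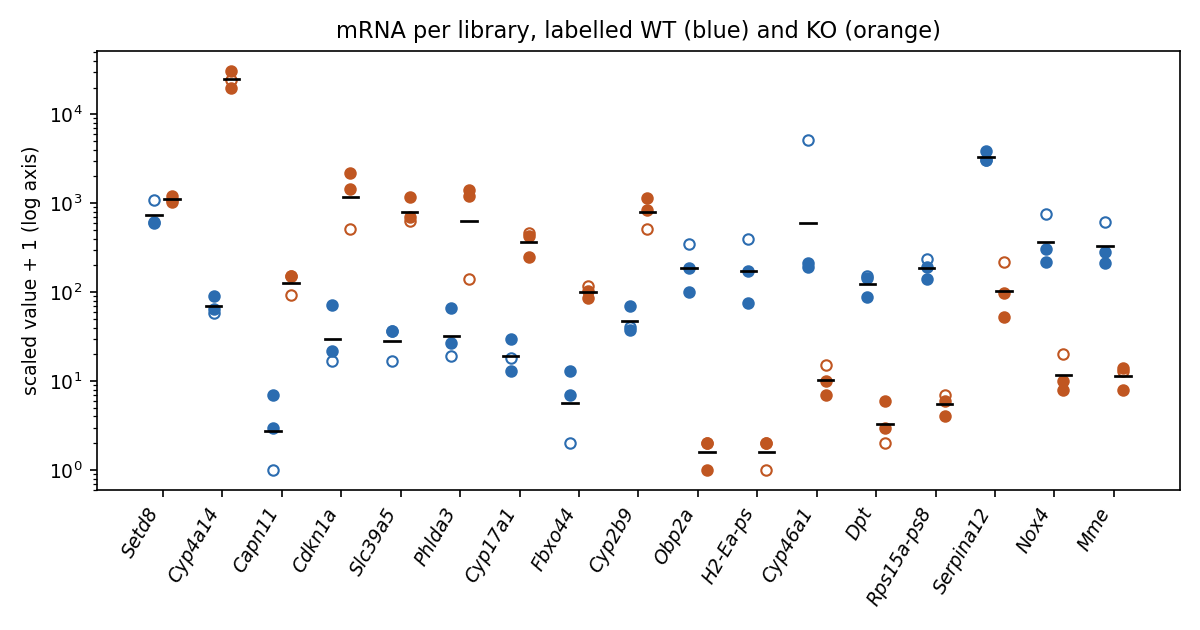
Scaled mRNA value plus 1 (log axis) per library for Setd8 and the 16 genes with the largest changes, WT in blue and KO in orange, with replicate 3 of each group as an open circle and the geometric mean of value plus 1 as a line. Setd8 overlapped between the groups, while Cyp4a14 lay between 58 and 90 in WT and between 19945 and 30918 in KO.

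The 3 WT and the 3 KO libraries did not overlap for 4379 genes, 26.0% of those tested, where chance gives 10%. The number of genes called depended on single libraries. It was 77 up and 77 down without WT replicate 1, 26 and 26 without WT replicate 2, 797 and 869 without WT replicate 3, 39 and 72 without KO replicate 1, 13 and 15 without KO replicate 2, and 162 and 128 without KO replicate 3. Without WT replicate 3, 226 of the 227 and 228 of the 228 genes remained called. Of 68 genes chosen by the naming rule besides Setd8, 13 kept their call whichever library was left out: Cyp4a14, Slc39a5, Cyp17a1, Cyp2b9, Gstm3, Ccnf, Obp2a, H2-Ea-ps, Dpt, Rps15a-ps8, Serpina12, Nox4 and Mme. The 68 held 30 calls without WT replicate 1, 16 without WT replicate 2, 67 without WT replicate 3 (all but Phlda3, limma adjusted p = 0.0737), 20 without KO replicate 1, 14 without KO replicate 2 and 41 without KO replicate 3.

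**Figure D2:**
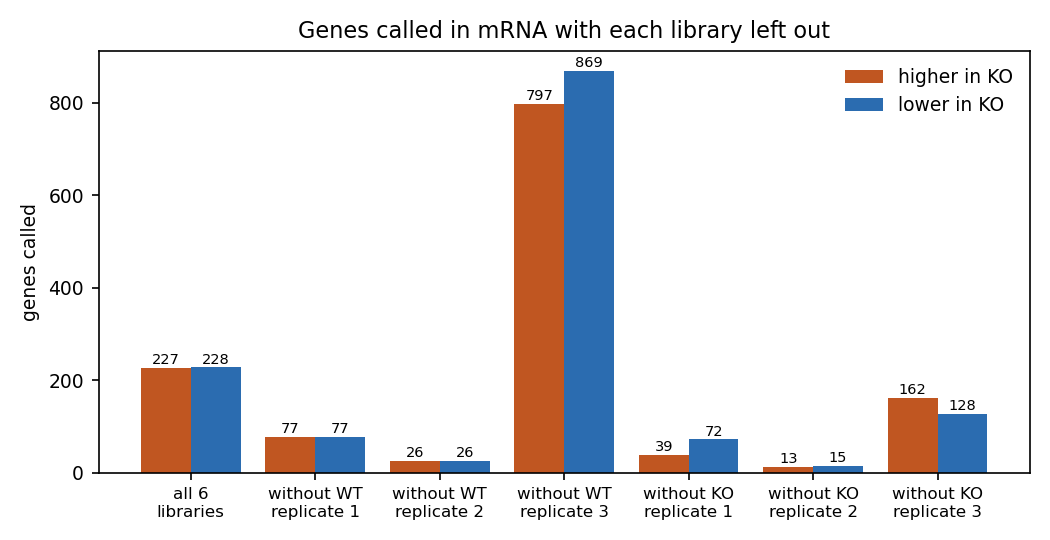
Number of genes called higher (orange) or lower (blue) in KO with all 6 libraries and with each library left out. The counts ranged from 13 up and 15 down without KO replicate 2 to 797 up and 869 down without WT replicate 3.

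The third comparison tested 45 gene lists fixed before the data were examined, of which 43 had at least 5 tested members. Genes of mitosis, female-biased liver genes and NRF2 targets were higher in KO as groups, and genes of lipogenesis, male-biased liver genes and the circadian clock were lower. These were among 13 lists called by camera with a preset correlation (Benjamini-Hochberg), and none of the 13 was called with an estimated correlation (adjusted p = 0.525 to 0.547). Of the 10 splits of the 6 libraries into 3 and 3, the real one and 2 others called 13 or more lists, those 2 with 26 and 27. With an estimated correlation 1 of the 43 lists had an unadjusted p under 0.05, and fry called 0 lists in 1 direction (12 at an unadjusted p under 0.05) and 27 for change in either direction. Each list's call below carries the adjusted p it had with an estimated correlation.

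Of 34 genes of mitosis, all 34 were higher in KO, with a median log2 fold change of 2.25 (camera adjusted p = 1.39e-16, and adjusted p = 0.525 with an estimated correlation). Among them 5 rose over all genes tested, 27 adjusted over the list alone, and 29 did not pass. Ccnf (cyclin F) rose 4.72-fold, Cdk1 8.07-fold, Prc1 5.15-fold and Aurka 3.97-fold, with KO replicate 3 lowest of the KO libraries for the last 3 (Cdk1 at 89, against 370 and 383, and 6.3-fold to 13.01-fold with a library left out). Without WT replicate 3, 11 rose. Among 23 replication-dependent histone genes, Hist1h1c rose 4.94-fold and 22 did not pass, with 5 adjusted over the list alone and a median of 0.77 (camera adjusted p = 7.74e-05, and adjusted p = 0.525 with an estimated correlation). Of 26 p53 targets, Cdkn1a and Phlda3 rose and 24 did not pass, with 7 up and 1 down adjusted over the list alone and a median of 0.69 (camera adjusted p = 0.00161, and adjusted p = 0.525 with an estimated correlation). Without WT replicate 3 the p53 list had 4 up and 1 down, and the histone list 7 up. None of the 33 genes of DNA replication (median 0.51) and none of the 23 of DNA repair and checkpoint (0.22) was called by limma.

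Genes that differ between the sexes in mouse liver moved in opposite directions. Of 15 female-biased genes, 6 rose and none fell, 10 adjusted over the list alone, with a median of 1.56 (camera adjusted p = 1.18e-05, and adjusted p = 0.525 with an estimated correlation). They included Cyp2b9, Cyp17a1 and Hao2 (13.2-fold), and 9 rose without WT replicate 3. Of 15 male-biased genes, 4 fell, 9 adjusted over the list alone, with a median of -1.03 (camera adjusted p = 1.77e-06, and adjusted p = 0.525 with an estimated correlation). These were the oxysterol hydroxylase Cyp7b1 (4.52-fold lower), Cyp4a12b (2.13-fold), Ugt2b38 (2.08-fold) and C6 (2.04-fold). Cyp4a and Ugt2b genes belong to families of similar sequence, so their values are uncertain. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were detected in all 6 libraries (Kdm5d at 231 to 288), and none of the 5 genes of X inactivation and the Y chromosome was called (median -0.30).

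Lipid genes fell in part. Of 18 lipogenic genes, 4 fell and 14 did not pass, 10 adjusted over the list alone, with a median of -0.65 (camera adjusted p = 3.26e-06, and adjusted p = 0.525 with an estimated correlation). Srebf1, which encodes the transcription factor SREBP-1, fell 3.23-fold, Acaca (acetyl-CoA carboxylase) 2.94-fold, Fasn (fatty acid synthase) 2.06-fold and Thrsp 6.39-fold. Of 24 genes of cholesterol synthesis and uptake, 3 fell, among them Insig1 (2.23-fold), and none rose, with 6 down and 1 up adjusted over the list alone. The cholesterol list was not called (camera adjusted p = 0.132), with a median of 0.0027 and a mean of -0.26, and 7 of its genes fell and 1 rose without WT replicate 3. In fatty acid oxidation and ketogenesis, Cyp4a14 and Cyp4a10 (12.7-fold, and 10.1-fold to 20.1-fold with a library left out), both PPAR alpha targets, rose and 29 of 31 did not pass. Cyp4a10 had 267, 258 and 1039 in WT. Of 25 genes of bile acid synthesis and transport, Hsd3b7 rose 2.32-fold, Cyp7b1 fell and 23 did not pass.

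Of 13 NRF2 targets, 4 rose and 9 did not pass, 6 adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.000793, and adjusted p = 0.525 with an estimated correlation). They were the glutathione transferases Gstm3 (6.31-fold) and Gsta1 (7.14-fold), Ephx1 (2.45-fold) and heme oxygenase Hmox1 (2.81-fold). Gstm1 among 17 conjugating enzymes (2.34-fold) and Cyp3a13 among 18 xenobiotic cytochrome P450 genes (3.43-fold) also rose. Among 19 clock genes, Arntl (8.45-fold) and Nr1d1 (3.61-fold) rose and 3 fell, among them Per3 (3.78-fold) and Tef (2.20-fold), with 3 up and 11 down adjusted over the list alone and a median of -0.90 (camera adjusted p = 0.000386, and adjusted p = 0.547 with an estimated correlation). Without WT replicate 3, 3 clock genes rose and 5 fell.

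Markers of macrophages and of stellate cells and fibroblasts were higher in KO as groups. Of 26 macrophage markers, Csf1r (3.14-fold) and Cd14 (3.69-fold) rose and 24 did not pass, with 13 up and 1 down adjusted over the list alone and a median of 1.08 (camera adjusted p = 3.26e-06, and adjusted p = 0.547 with an estimated correlation). Without WT replicate 3, 8 rose. Of 24 stellate cell and fibroblast markers, Pdgfrb (2.56-fold) and Postn (2.54-fold) rose, Dpt fell and 21 did not pass, with 4 up and 1 down adjusted over the list alone and a median of 0.76 (camera adjusted p = 0.000256, and adjusted p = 0.525 with an estimated correlation). Spp1 (osteopontin, 3.6-fold) rose among 20 cholangiocyte and ductal markers. Vcam1 (2.16-fold) and Ccl6 (3.5-fold) rose among 10 genes of inflammatory cytokines and adhesion. None of 20 endothelial (median 0.14), 17 lymphocyte (0.34), 8 neutrophil (0.27) and 22 interferon response genes (0.010) was called by limma.

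Among 16 genes of the unfolded protein response, Manf fell 2.01-fold and 15 did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.00337, and adjusted p = 0.525 with an estimated correlation), and the list was not called without WT replicate 2 (adjusted p = 0.0545). Among 16 immediate early genes, Jun fell 2.17-fold and 15 did not pass, with 1 adjusted over the list alone (camera adjusted p = 0.0171, and adjusted p = 0.547 with an estimated correlation), and the list was not called without WT replicate 2 (adjusted p = 0.124) or WT replicate 3 (0.0736). The medians of these lists were -0.40 and -0.44. None of 13 pericentral genes was called by limma over all genes and 5 adjusted over the list alone, with a median of 0.56 (camera adjusted p = 0.0123, and adjusted p = 0.525 with an estimated correlation). That list was not called without WT replicate 2 (adjusted p = 0.0871).

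In lists that were not called as groups, C4b (complement, 3.55-fold), Lcn2 (lipocalin 2, 11.3-fold), Lbp (2.16-fold), Vldlr (2.52-fold), Ndrg1 (3.14-fold), P4ha2 (2.32-fold) and Leo1 (2.77-fold) rose. Pklr (liver pyruvate kinase, 3.07-fold), Fetub (2.80-fold), Kng1 (2.18-fold), Mt2 (metallothionein 2, 5.57-fold) and Vegfa (2.10-fold) fell. They were the called members, with C6, of 33 coagulation and complement genes, 22 acute phase, 17 integrated stress response, 12 hypoxia, 27 Pol II pausing and elongation, 12 glycolytic and 29 plasma carrier genes. C4b lies in the major histocompatibility region, where another haplotype in one group stays open. The hypoxia list had a median of 0.12 and a mean of -0.01. Among metabolic lists without a called gene, the median was -0.12 for 35 genes of amino acid breakdown, 0.01 for 11 of the urea cycle, -0.17 for 15 of gluconeogenesis and glycogen, -0.0040 for 20 of the TCA cycle, -0.07 for 44 of oxidative phosphorylation and 0.11 for 14 periportal genes. It was -0.11 for 20 hepatocyte transcription factors, 0.73 for 9 fetal liver genes and 0.08 for 14 glycolytic isoforms of other cells. Across the 17 lists with no called gene, 59 of 323 members had an unadjusted limma p under 0.05, as had 3361 of all 16813 genes tested. Of these members edgeR called 1 and DESeq2 called 25. The lists of H4K20 methylation and of erythroid markers, with 4 tested members each, were too small.

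**Figure D3:**
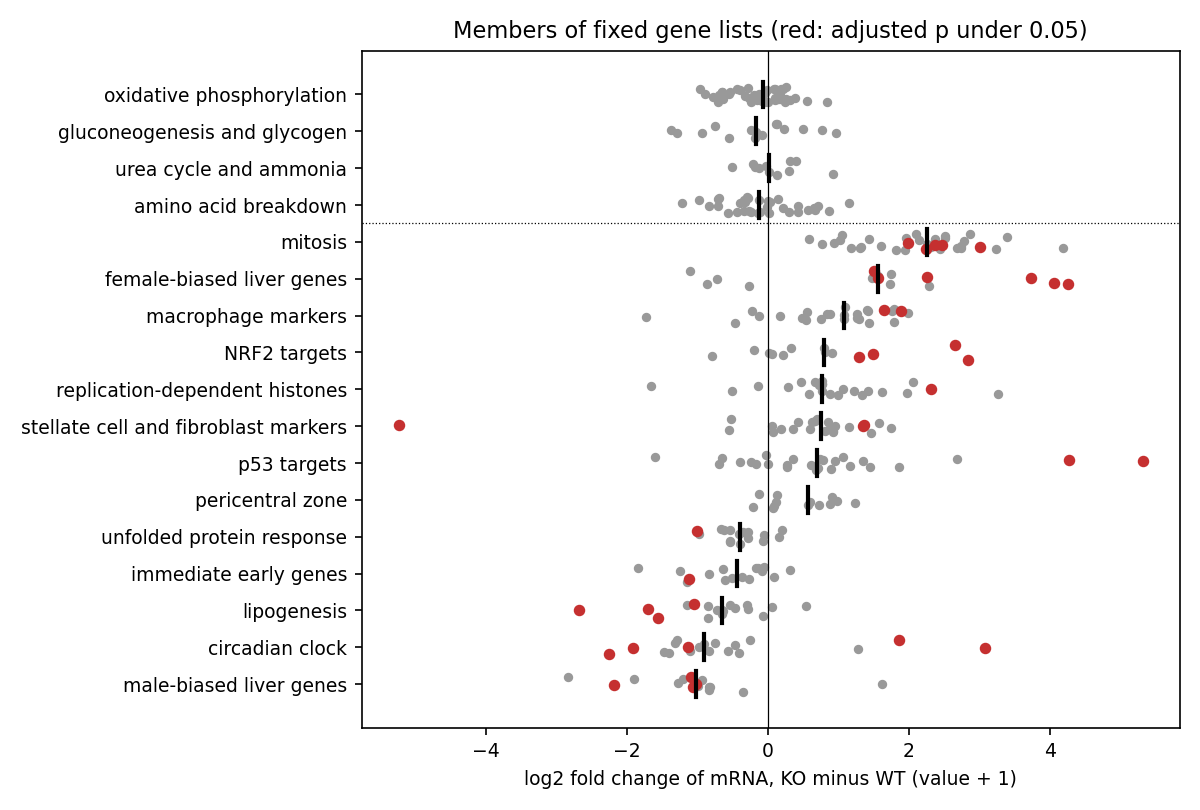
Log2 fold change of mRNA, KO minus WT, for each tested member of the 13 called lists (below the dotted line) and of 4 metabolic lists without a called gene, with called genes in red and list medians as black lines. All 34 genes of mitosis lay above 0, while oxidative phosphorylation had a median of -0.07.

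The fourth comparison asked whether newly made RNA moved with mRNA and which gene groups differed in it. The median nascent RNA of genes that rose in mRNA was higher in KO in both methods, and that of genes that fell was lower. Over 175 genes that rose, the median centred log2 ratio was 0.51 in EU and 0.51 in Br, with 61.7% and 80% of genes above 0. Over 173 genes that fell it was -0.61 in EU and -0.45 in Br. With mRNA sets called without WT replicate 3, chosen after the data were seen, it was 0.35 and 0.34 for genes that rose and -0.39 and -0.34 for genes that fell. Each of these medians lay outside all or nearly all of 10000 random lists matched on mean RPKM, at percentile 100 for genes that rose and 0 for genes that fell. With 1 library per genotype no test was made, and intervals cover counting error only.

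Across genes, which are not independent replicates, mRNA and nascent change were weakly related. The Spearman correlation was 0.175 between mRNA and EU and 0.195 between mRNA and Br over 11882 genes, and 0.118 between EU and Br over 13213 genes. At least 2-fold differences of the same sign in both methods, with at least 20 reads in each, were found for 214 genes higher and 152 lower in KO, while 148 genes had opposite signs. Of 62 genes named in mRNA that had nascent values, 47 had the sign of the mRNA change in EU, 49 in Br and 40 in both. Cyp17a1, C4b and Lbp, which rose in mRNA, and Jun, which fell, went the other way in both methods with intervals that exclude no change. Cyp17a1 had 159 EU reads in WT and 2 in KO (log2 interval -8.34 to -3.41) and a Br interval of -1.35 to -0.08. C4b had log2 ratios of -1.045 in EU and -0.524 in Br, and Jun 1.04 and 0.98.

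By gene group, nascent RNA of lipogenesis, cholesterol synthesis and uptake, the urea cycle, amino acid breakdown, the acute phase, the unfolded protein response and periportal genes was lower in KO in both methods. The median of 18 lipogenic genes was -1.63 in EU and -0.84 in Br, that of 23 cholesterol genes -1.58 and -0.30, and that of 35 genes of amino acid breakdown -0.93 and -0.71. It was -1.38 and -0.63 for 11 genes of the urea cycle, -1.45 and -0.77 for 14 periportal genes, -0.67 and -0.41 for 22 acute phase genes and -0.80 and -0.39 for 16 genes of the unfolded protein response. The periportal list shares Hal, Sds and Uroc1 with amino acid breakdown and Gls2, Cps1, Ass1 and Arg1 with the urea cycle. Its median is therefore not a separate result. Nascent RNA was higher in both methods for 20 stellate cell and fibroblast markers (2.46 and 0.87), 28 genes of mitosis (1.80 and 0.77), 14 cholangiocyte and ductal markers (1.76 and 0.74), 25 p53 targets (0.56 and 0.34) and 14 immediate early genes (1.07 and 0.32). Each of these lists lay outside the central 95% of random lists in both methods. With genes from a mean RPKM of 0.2 kept, immediate early genes lay at percentile 94.6 in Br and were no longer outside. In mRNA that list lay in the opposite direction, with a median of -0.44, called by camera with the preset correlation only. The median gene of the mitosis list had 61 EU and 34 Br reads over both libraries.

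**Figure D4:**
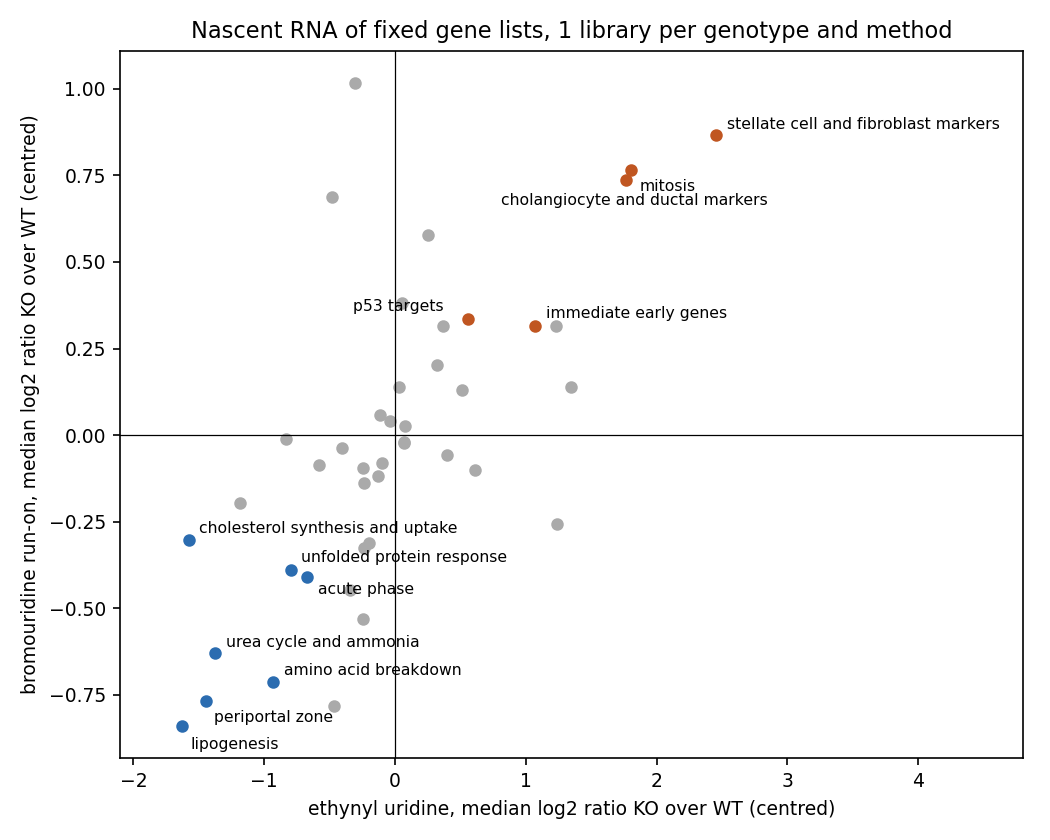
Median centred log2 ratio of nascent RNA, KO over WT, of each fixed gene list by ethynyl uridine (horizontal) and by bromouridine run-on (vertical), with lists named higher in orange, lower in blue and others in grey. Lipogenesis lay at -1.63 and -0.84, and stellate cell and fibroblast markers at 2.46 and 0.87.

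The remaining lists were not outside the bounds in both methods. Outside in EU alone, fatty acid oxidation had a median of 1.34, male-biased genes -1.18, xenobiotic cytochrome P450 genes -0.83, bile acid genes -0.58, inflammatory genes 1.23, fetal liver genes 1.24 and the integrated stress response 0.61. Of these, fetal liver genes (-0.26) and the integrated stress response (-0.10) had the opposite sign in Br. Outside in Br alone, female-biased genes had a median of 1.02, the circadian clock -0.78, interferon response 0.69, pericentral genes 0.58, gluconeogenesis and glycogen -0.53, hypoxia -0.45 and coagulation and complement -0.31. Of these, female-biased genes (-0.31) and interferon response (-0.48) had the opposite sign in EU. Inside the bounds in both methods were H4K20 methylation (0.51 in EU and 0.13 in Br), pausing and elongation factors (-0.12 and 0.06), glycolysis (-0.24 and -0.33), glycolytic isoforms of other cells (0.40 and -0.06), conjugating enzymes (-0.40 and -0.04), NRF2 targets (0.37 and 0.32), the TCA cycle (-0.13 and -0.12), oxidative phosphorylation (0.03 and 0.14) and plasma carriers (-0.10 and -0.08). So were hepatocyte transcription factors (-0.24 and -0.14), DNA repair (-0.25 and -0.09), DNA replication (0.07 and 0.03), macrophage (0.32 and 0.20), lymphocyte (0.07 and -0.02), neutrophil (0.06 and 0.38) and endothelial markers (-0.04 and 0.04) and histones (0.07 and -0.02).

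Single genes with large differences in both methods included Cyp4a14, with 2 EU reads in WT and 3564 in KO (95% counting interval of the log2 ratio 9.97 to 14.87) and 10 and 1447 Br reads (6.74 to 8.69), and the pantetheinase Vnn1, with 48 and 451 EU reads (3.83 to 4.72) and 2 and 66 Br reads (3.58 to 8.57). Fmod (2 and 93 EU reads) and Slamf6 (1 and 48) were higher in both, with 0 Br reads in WT and 8 and 6 in KO and 95% counting intervals of the log2 ratio from 4.67 and 4.07 in EU and from 1.22 and 0.68 in Br. Meox2 (226 and 1 EU reads) and Bdh2 (43 and 0) were lower in both, with 23 and 18 Br reads in WT and 0 and 1 in KO and intervals up to -4.30 and -2.45 in EU and up to -2.08 and -1.06 in Br. Genes that the rule also chose had intervals that include no change in 1 or both methods. Cyp2b19 had 1 and 17 EU reads (interval from 2.44) and 0 and 4 Br reads (from -0.15), 4930519F09Rik had 61 and 0 EU reads (up to -2.98) and 5 and 0 Br reads (up to 0.57), and Chgb had 6 and 0 reads in both (up to 0.79 in EU and 0.21 in Br). With at least 20 reads in each method, Thrsp was among the lowest, at 9572 and 993 EU reads (interval -2.34 to -2.15) and 424 and 43 Br reads (-3.34 to -2.40).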

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

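Tests with array weights, other pseudocounts in mRNA, TMM scaling, edgeR with TMM, edgeR without WT replicate 3, read minimums and mRNA sets without WT replicate 3 were chosen after the results were seen. Genes higher and lower in KO (227 and 228) became 500 and 514 with the replicate block, 4250 and 4160 with array weights, 890 and 1106 with edgeR without WT replicate 3 and 819 and 829 with DESeq2. Leaving out 1 library gave 13 to 797 higher and 15 to 869 lower. The cause was not tested, beyond the smaller number of libraries where 1 is left out. The replicate numbers were not used as pairs, since deviations from the group mean correlated at 0.409, -0.242 and 0.198 for the same number and WT replicate 2 correlated best with KO replicate 1 (0.238). Other splits of the 6 libraries called 0 genes by limma against 455 in the real split. At an unadjusted p under 0.05 they gave 82 to 2887 genes against 3361, and 10 splits are too few for a share under 0.05.

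The Setd8 log2 difference of 0.59 was positive under every alternative run (0.44 to 0.87 with a library left out), and passed the threshold at 0.87 without WT replicate 3, 0.76 with array weights and 0.90 with edgeR without WT replicate 3, against adjusted p values above it otherwise. Camera called 13 lists, 10 to 23 with a library left out (23 without KO replicate 3), 0 with an estimated correlation and 0 with fry. The cause was not tested. For nascent RNA, the EU median of genes lower in mRNA was -0.39 and the Br median of genes higher in mRNA was 0.34 with mRNA sets without WT replicate 3. The Spearman correlation between EU and Br was 0.0984 at a mean RPKM of 0.2, 0.147 at 5 and 0.181 with at least 20 reads, and that between mRNA and EU was 0.151 without WT replicate 3. The cause was not tested. Of values of single genes and lists, 257 in mRNA lost their call under alternatives fixed in advance and 3 under those added later. The EU median of mitosis moved to 3.03 at a mean RPKM of 5, and none changed sign. Unchanged were 870 and 481 values. For mRNA this means the same direction and side of the threshold. For nascent lists it means a median inside the interval of the main median. A nascent list that left the naming bounds, such as immediate early genes in Br, is thus not counted as lost. The median of all genes was -0.12 with DESeq2 and 0.0023 in the fit reported. At the depth, spread and number of these libraries, 2-fold changes were recovered for 17 of 100 genes simulated with independent noise.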

Other observations

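Tests of chance by other splits, of the clock phase and of WT replicate 3 as its source, of interferon signalling, of reads of class I genes, of neighbouring genes, of the hepatocyte share and of gene length were chosen after the result was seen. Camera called 13 lists in the real split and up to 27 in other splits, with 3 of the 10 splits at 13 or more. For genes, 1 of the 10 splits (the real one, 455 genes) gave as many calls, and the highest other gave 0. In both cases 10 splits are too few for a share under 0.05.

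Class II genes of the major histocompatibility region were chosen for mention after their values were seen. H2-Aa had scaled values of 181, 277 and 533 in WT and 1556, 2434 and 396 in KO (limma adjusted p = 0.154), with KO replicate 3 inside the WT range. H2-Eb1 had 272, 320 and 322 against 1929, 2297 and 377 (limma adjusted p = 0.126), without overlap. H2-Eb2 (log2 -1.48) and H2-Oa (-1.17) lay lower in KO and were not called either. Called genes lay next to each other in 25 pairs, where 10000 permutations of gene order gave a median of 12 and at most 27. Families of similar sequence were not set apart in this count, so it does not show an effect of region. Of 40 tested neighbours of Kmt5a, 2 were called, while 2.70% of genes outside the H2 region were called.

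Of 19 clock genes, 2 rose and 3 fell in mRNA, and the list's call was lost with an estimated correlation (adjusted p = 0.547). WT replicate 3, the library that stood apart, is argued against as the source: without it, 18 of the 19 kept their sign and the median log2 change in the same direction was 0.985 (quartiles 0.59 and 1.32), against 1.14 with all libraries. This replaced a test by the number of calls, which rose in all genes without that library. Livers taken at another time of day, or with the clock at another phase, may account for the change, since 12 of 15 genes given a phase lay on the side of an earlier phase in KO, with 10 of 10 evening genes lower but 2 of 5 morning genes higher. That tally left out 4 clock genes, among them Nr1d1, which rose, and it became 13 of 16 with Nr1d1 counted as a morning gene and 12 of 16 as an evening gene, on either side of the bound of 4 in 5, so it leaves the explanation open. In nascent RNA, 8 of 14 lay on that side in EU and 12 of 14 in Br, the labels used here give no hour of collection, and an effect of the knockout on the clock was not tested.

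Of 33 tested H2 genes, H2-Ea-ps, H2-K2 and H2-Bl fell and none rose, and without WT replicate 3 the count was 11 lower and 0 higher (limma). Of those gained, H2-M2 (476, 484 and 6 in WT, 185, 95 and 84 in KO), H2-M3, H2-M5 and H2-T3 had WT replicate 3 below every KO library. It lay inside the KO range for H2-Q2 and H2-Q6, while H2-T24 and H2-Q3 did not overlap between the groups. The larger count thus in part reflects a split among the WT libraries. Weaker interferon signalling is argued against by a median of 0.010 over 22 interferon response genes, with quartiles of -0.16 and 0.29. Another haplotype of the region in one group may account for the falls, but 3.64% of its 110 other genes were called against 2.70% elsewhere (Fisher's exact p = 0.545, two-sided), which leaves it open. The 4 called, named after their values were seen, were Msh5, which fell, and Atat1, C4b and Cyp21a2-ps, which rose. Cyp21a2-ps, at 0 in every WT library and 53, 41 and 27 in KO (limma adjusted p = 0.0136), goes with such a difference. For H2-K2 and H2-Bl, though not for the class II pseudogene H2-Ea-ps, reads moved between similar class I genes could too. Their sum cannot show this, since the loss of H2-K2 and H2-Bl was 2.79% of the mean summed class I value in WT, against an SD of 15.5% between WT libraries. For H2-K2 and H2-Bl these explanations cannot be told apart, since few genes of the region were called and no sequence reads were used here.

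Nascent RNA of 46 genes of amino acid breakdown and the urea cycle was lower in KO, with 42 below 0 in EU (median -0.99) and 43 in Br (-0.67), while none was called in mRNA by limma (median -0.07; 7 at an unadjusted p under 0.05, 0 called by edgeR and 4 by DESeq2). A smaller share of hepatocyte RNA would lower genes of hepatocytes alike. Plasma carrier genes had medians of -0.102 in EU (quartiles -0.465 and 0.165) and -0.08 in Br (-0.244 and 0.195), which argues against it as the sole source of this fall. Their percentiles of 54.4 in EU and 50.8 in Br cannot decide this, since random lists matched on mean RPKM may hold hepatocyte genes too. Other lists of hepatocyte genes spread to both sides in EU. Medians were -0.83 in EU and -0.01 in Br for xenobiotic cytochrome P450 genes and -0.58 and -0.09 for bile acid genes. For fatty acid oxidation they were 1.34 and 0.14. A smaller hepatocyte share as a part of the fall thus stays open. Markers of other cells moved apart, with medians of 2.46 in EU and 0.87 in Br for stellate cells and fibroblasts, 1.76 and 0.74 for cholangiocytes, 0.32 and 0.20 for macrophages and -0.04 and 0.04 for endothelium, so a change in the cell types that were higher stays open. Gene length is argued against, since over 20 bins of genomic span the lowest median of all genes was -0.139 in EU and -0.085 in Br, while the upper quartiles of the 46 genes were -0.487 and -0.444. Earlier versions gave no verdict: matching on transcript length moved nothing, and taking off the span trend left a percentile of 0 in both methods but bin medians in Br lay only 0.139 apart, so that the bound was rewritten after this was seen. Uneven depth of the KO and WT libraries was examined by thinning reads to the smaller library, which left a percentile of 0 in both methods. Thinning keeps the expected ratio of a gene, and the median gene of these lists had 3447 (amino acid breakdown) and 4714 (urea cycle) EU reads, so this test could not decide on depth. With 1 library per genotype, a difference by genotype and a difference between single animals both stay open, untested.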
